A study of Mus musculus with 13 samples.

How the data were processed

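RNA was measured by poly-A selected, strand-specific paired-end sequencing in splenic B cells of C57BL/6 background, stimulated with lipopolysaccharide (LPS), a bacterial ligand of Toll-like receptor 4 (TLR4), at 25 µg/ml for 48 h, per the labels. The reads were 76 bases long. B cells were enriched by removing CD43-positive cells, a step meant to take out T cells, myeloid cells, activated B cells and CD43-positive progenitor cells. The 13 libraries fall into 7 WT and 6 Whsc1-KO by their labels, and the series' design text calls them independent biological replicates.

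The authors deposited a table of normalized counts per gene. Per the file headers the columns carry a genotype and a replicate number, and each matched 1 sample by name. Per the submitters' processing notes, STAR 2.5.1b, RSEM 1.2.28 and DESeq2 1.10.1 and the builds GRCm38 and mm9 were used, with no role given for any of them. The deposited signal values are gene counts divided by 1 size factor per library and rounded: in each library 100% of the values were whole multiples of a single step, within a tolerance of 0.05 reads. The recovered totals ran from 38881663 to 53019516 reads in genes per library. The authors also deposited a differential expression table with a log2 fold change, a Wald score and a p-value per gene, a list of genes, and enrichment tables of gene ontology terms and KEGG pathways with a fold enrichment (a ratio) and p-values per the file headers. The list held 8116 genes, the same as those with an adjusted p under 0.05 in the authors' deposited table. The enrichment tables were used only for the pathway counts given under other observations.

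The test was limma 3.58.1 with a mean-variance trend on log2(deposited normalized count + 1), for the 13947 genes with a normalized count of 10 or more in at least 6 libraries; the other 33696 were left out, 22536 of them without a read in any library. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with few reads. Normalized values are not counts, so edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. The fits ran in R 4.3.3, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and plots. The 33 gene lists, the tests and most alternatives were fixed before the data were examined. The 29 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, which asks whether the members of a list move and does not compare them with other genes. Adjusted p of lists are over the 29 lists. Where 2 identifiers shared a symbol, the symbol stands for the one with the higher mean.

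Genes are named by a rule of 5 parts, also fixed beforehand. The parts are Whsc1 with Nsd1, Whsc1l1 and Setd2; the 10 largest positive and 10 largest negative log2 fold changes past the threshold with a mean of 100 or more in a group, leaving out antigen receptor segments, sex-linked genes and predicted genes; up to 4 members with the smallest adjusted p from each biological or cell type list; all tested heavy chain constant region genes; and up to 3 members of each technical list. The rule gave 142 genes, and those named outside it are said to be so. Symbols come from the deposited table. Coordinates and genomic spans come from the GENCODE M21 annotation of GRCm38, to which 47224 of 47643 gene identifiers (99.1%) matched.

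The tests were tried on simulated counts for the 13947 genes, with 50 genes changed at each of 4 folds and a small list of genes raised besides. Limma called 4% of genes changed 1.25-fold, 34% of those changed 1.5-fold, 88% of those changed 2-fold and 98% of those changed 4-fold, and 3.8% of its calls were false. DESeq2 called 92% at 2-fold with 17.1% false calls, and edgeR 86% with 4.5%. The Wilcoxon test called 0% at each fold in that setting, where few genes were changed. Far more genes were called in the data, and the simulation held no difference in sex or RNA of other cells. The shares called and false therefore do not carry over to the real calls. Libraries of a group were checked for duplicates: the closest pair, Whsc1-KO replicates 4 and 5, had a chi-square of 26.8 per gene, far from sampling noise alone. Alternatives covered the pseudocount, the filter, the scaling, library weights, other tests, a replicate block, a sex score built from Xist and Y-linked genes, other thresholds, genes left out and each library left out. A further 5, on sets of replicates, were chosen after seeing the data.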

Results

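The series compared B cells that lack Whsc1, a histone H3 lysine 36 methyltransferase of the NSD family, with WT B cells, to find the genes and pathways that depend on Whsc1. Loss of the gene is lethal in embryos, so fetal liver cells of WT or Whsc1-KO littermates were used to rebuild the blood system of irradiated RAG1-KO mice, which make no mature lymphocytes of their own. Splenic B cells from these mice were then stimulated with LPS, which makes them divide and switch antibody class. The 7 WT libraries held 38881663 to 53019516 reads in genes and the 6 Whsc1-KO libraries 39101317 to 49443099. Within a group, Pearson's r of log2 values across genes was 0.976 or more in WT and 0.960 or more in Whsc1-KO; genes are not independent replicates. The first principal component held 48.5% of the variance and ran from -50.4 to -27.2 in WT and from 18.7 to 71.2 in Whsc1-KO. The second held 16% and set Whsc1-KO replicates 1 to 3 apart from replicates 4 to 6. Results without those last 3 libraries, and within replicates 1 to 3 or the later ones, are given below and were chosen after the data were seen.

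Whsc1 itself (chromosome 5, 33820725 to 33897975, plus strand, GRCm38) was lower in Whsc1-KO but still present. Its mean normalized count was 6613 ± 718 (SD, n = 7) in WT and 4562 ± 624 (SD, n = 6) in Whsc1-KO, or 69% of the WT level, with a log2 fold change of -0.54 (SE 0.09, limma adjusted p = 0.00049). The ranges did not overlap: WT libraries lay between 5537 and 7459 and Whsc1-KO libraries between 3733 and 5261. The log2 fold change was -0.84 within replicates 1 to 3 and -0.27 within the later replicates. A count over the whole gene does not show which exons were transcribed, so it does not test the deletion itself. The paralogs Nsd1 and Whsc1l1 had log2 fold changes of -0.24 and -0.34, and Setd2, the main enzyme for trimethylated lysine 36, had -0.41 (limma adjusted p = 0.00848, 0.00247 and 0.00289). Of the 7 genes in the list of lysine 36 methyltransferases 6, Whsc1 included, fell and 1, Smyd2, rose by 0.32 (named after its value was seen). The counts adjusted over the list alone were the same. As Whsc1 is the targeted gene, the list in part restates the knockout. The list's camera adjusted p of 0.0302 became an adjusted p = 0.586 with an estimated correlation. Leaving out Whsc1-KO replicates 4 to 6, Nsd1, Whsc1l1, Setd2 and the list no longer passed (adjusted p = 0.186, 0.064, 0.0563 and 0.051), with log2 fold changes of -0.12, -0.23 and -0.19 for the genes, while Whsc1 did, at -0.71.

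Much of the transcriptome differed between Whsc1-KO and WT B cells, with homeobox genes of the Hoxa cluster and long genes such as Gphn at the extremes. Most members of the cell division, oxidative phosphorylation and MYC target and ribosome biogenesis lists were higher, and most of the mature B cell identity list lower, though each of these lists had an adjusted p = 0.586 with an estimated correlation. Of 13947 genes tested by limma, 3636 were higher and 3588 lower in Whsc1-KO. At a log2 fold change of 1 or more in size, 679 were higher and 717 lower. The authors' deposited table lists 4337 genes higher and 3779 lower; 3589 of the higher and 3497 of the lower genes here are also called there in the same direction, and 0 in opposite directions. Leaving out Whsc1-KO replicates 4 to 6, 1947 were higher and 2177 lower, of which 1788 and 1966 were among the genes called with all libraries. Within replicates 1 to 3, 947 genes were higher and 1222 lower, and within the later replicates 4184 and 4196. By Xist and Y-linked genes WT replicates 1 to 3 were all female and Whsc1-KO replicates 1 to 3 all male, so genotype and sex cannot be told apart within them, and the fit without Whsc1-KO replicates 4 to 6 sets male Whsc1-KO libraries against WT libraries of both sexes.

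The largest increases were in Hoxa genes, which encode transcription factors active in blood stem and progenitor cells. Hoxa7 rose from 2.70 ± 2.07 (SD, n = 7) in WT to 707 ± 186 (SD, n = 6) in Whsc1-KO, a log2 fold change of 7.79 (SE 0.40, limma adjusted p = 3.36e-08). Hoxa5 rose by 6.60, Hoxa3 by 6.40 and Hoxa6 by 6.09 on the log2 scale. In each of these 4 genes the lowest Whsc1-KO library lay above the highest WT library: for Hoxa7, 477 against 5.26, and for Hoxa3, 215 against 6.31. No WT library reached the filter's minimum of 10 in these genes, so the filter fixed that they would not overlap, though not the size of the gap. They lie on chromosome 6 between 52169062, where Hoxa3 starts, and 52221854, where Hoxa7 ends. In the fit without Whsc1-KO replicates 4 to 6 Hoxa7, Hoxa5, Hoxa3 and Hoxa6 had log2 fold changes of 7.48, 6.14, 6.39 and 5.66. Shtn1, a neuronal cytoskeletal regulator, rose by 4.62 and the chemokine receptor gene Cxcr3 by 4.18 (adjusted p = 4.91e-05 and 8.78e-06). The other 4 of the 10 largest increases were the erythroid genes Alas2, Hba-a1, Hba-a2 and Hbb-bs, described with the erythroid markers.

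Among the largest decreases, Cntln, a centrosomal protein gene, went from 273 ± 51.4 (SD, n = 7) to 2.68 ± 1.93 (SD, n = 6), a log2 fold change of -6.42 (SE 0.36, limma adjusted p = 5.98e-08). Its highest Whsc1-KO library had 5.42 normalized counts, below the filter's minimum of 10, so the filter fixed its direction, though not its size. The ciliary transcription factor gene Rfx3 had a log2 fold change of -5.87, the mitochondrial carrier gene Slc25a13 -5.31 and the polarity gene Pard3b -4.88. Gphn, which encodes the scaffold protein gephyrin, went from 1937 ± 328 (SD, n = 7) to 78.8 ± 24.3 (SD, n = 6; log2 fold change -4.64, SE 0.17, limma adjusted p = 1.06e-09). Klf8, Tnik, Chic1, Armcx4 and BC026585 completed the 10 largest decreases, at -4.68 to -3.57. Klf8 was uneven in WT, where replicate 3 had 1272 normalized counts and the other libraries 158 to 275.

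**Figure D1:**
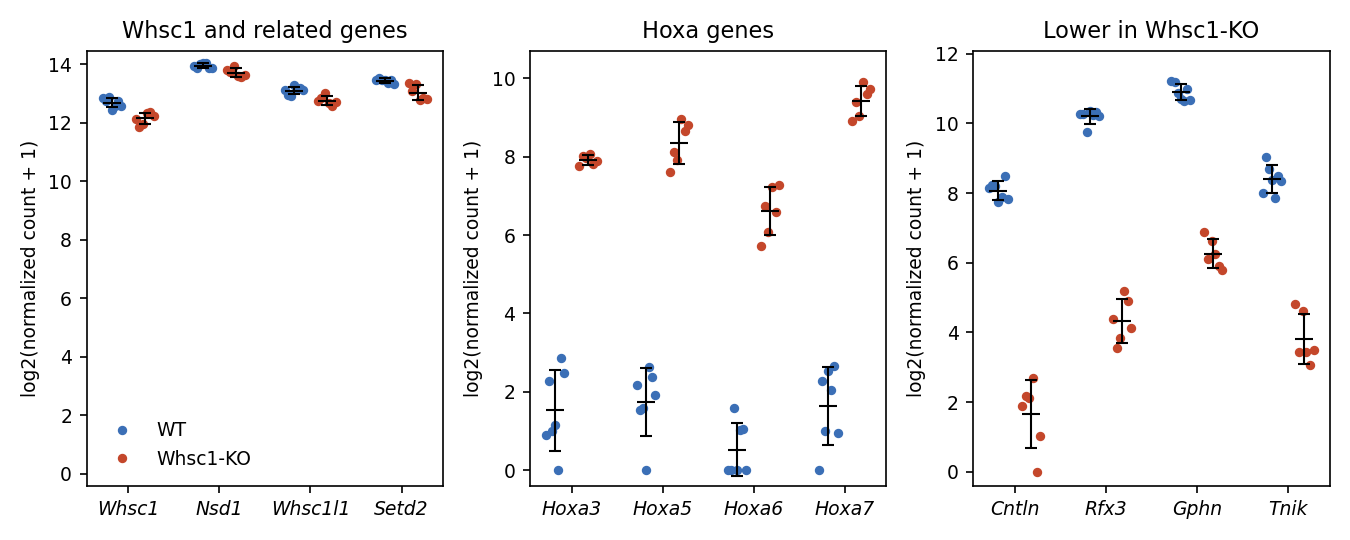
Points are log2(normalized count + 1) of 12 genes in each of the 7 WT (blue) and 6 Whsc1-KO (red) libraries, with bars for the mean ± SD. Whsc1 differs by -0.54 in the mean, while Hoxa7 differs by 7.79 and Cntln by -6.42.

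Long genes were more often lower. Among protein-coding genes with a genomic span under 10 kb 37.7% were higher and 16.6% lower, and among those over 200 kb 11.7% were higher and 49.8% lower. The median log2 fold change went from 0.14 to -0.35 between these classes, and from 0.12 to -0.24 when Whsc1-KO replicates 4 to 6 were left out. Genes called lower with a log2 fold change of -2 or less had a median span of 89.5 kb, against 23.2 kb for all protein-coding genes tested. Across 11988 genes, which are not independent replicates, the Spearman correlation of fold change with span was -0.216, and -0.11 given transcript length, GC content and mean level.

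**Figure D2:**
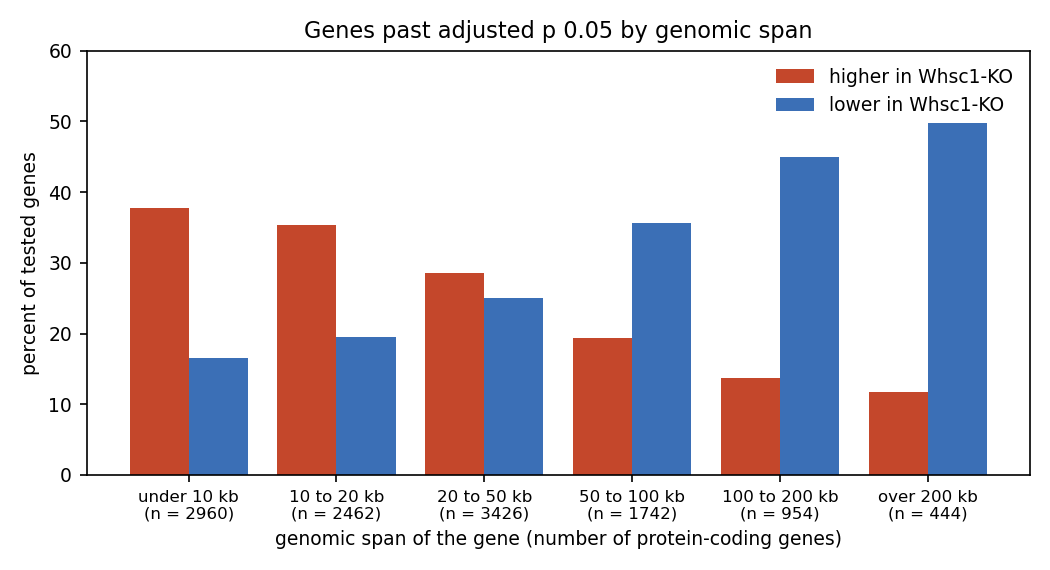
Bars are the percent of tested protein-coding genes past the threshold, higher (red) or lower (blue) in Whsc1-KO, in 6 classes of genomic span with the number of genes in each. The share lower goes from 16.6% under 10 kb to 49.8% over 200 kb.

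Genes of cell division rose together in Whsc1-KO. In the list of G2/M and mitosis genes 38 of 40 tested members were higher and 0 lower, with a median log2 fold change of 0.77 (39 higher adjusted over the list alone). Cdc20 and Ube2c, which drive exit from mitosis, rose by 1.12 and 1.07, and the proliferation marker Mki67 rose from 32725 ± 4371 (SD, n = 7) to 54706 ± 9168 (SD, n = 6; log2 fold change 0.74, limma adjusted p = 0.000227). In the list of G1/S and DNA replication genes 45 of 52 were higher and 0 lower, with a median of 0.605 (46 higher adjusted over the list alone). They included the cyclin gene Ccne1 at 1.23, the replicative helicase subunit Mcm5 at 0.93 and the ribonucleotide reductase subunit Rrm2 at 1.17. The lists had camera adjusted p of 7.09e-12 and 1.92e-11, and each an adjusted p = 0.586 with an estimated correlation. Leaving out Whsc1-KO replicates 4 to 6, 29 of the G2/M and 26 of the G1/S genes were higher, with medians of 0.42 and 0.34, and Mcm5 and Rrm2 were at 0.62 and 0.68. Within replicates 1 to 3, 11 and 5 genes were higher, with medians of 0.28 and 0.16, and WT replicate 3 had list scores of 0.26 and 0.26 against 0.26 and 0.24 in Whsc1-KO replicate 3. The series' text states a proliferation defect, with changes found by flow cytometry that were not analysed here. Higher RNA of these genes does not by itself show more division, which was not measured here.

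Genes that restrain the cycle were both higher and lower. In the list of CDK inhibitors and cyclin D genes 7 of 15 were higher and 1 lower, both over all genes and adjusted over the list alone. Cdkn2a rose from 389 ± 113 (SD, n = 7) to 1830 ± 755 (SD, n = 6; log2 fold change 2.18, SE 0.26, limma adjusted p = 3.80e-05), Cdkn1a by 1.45 and Cdkn2b by 1.11, while the inhibitor gene Cdkn1b had a log2 fold change of -0.70. Those higher also included Cdk4 and Ccnd3, which promote the cycle and were named after their values were seen; Ccnd3 went from 0.48 to 0.21 without Whsc1-KO replicates 4 to 6. Of 27 tested p53 target genes 13 were higher and 4 lower, the same adjusted over the list alone. Phlda3 rose by 1.34 and Zmat3 by 0.62, and the death receptor gene Fas had -1.80; the others lower, named after their values were seen, were Sesn1, Polk and Gadd45a. These did not pass without Whsc1-KO replicates 4 to 6: Sesn1 and Gadd45a went from -0.76 and -0.37 to -0.22 and -0.15, while Polk went from -0.18 to -0.21. The camera adjusted p of these lists were 0.0262 and 0.0369, with an adjusted p = 0.586 with an estimated correlation for both. Neither passed in the fit without Whsc1-KO replicates 4 to 6 (adjusted p = 0.129 and 0.192).

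In the list of homologous recombination and replication stress genes 28 of 35 were higher and 2 lower (3 lower adjusted over the list alone), with Fanca at 0.80 and Brca1 at 0.81. The lower genes were the checkpoint kinase Atr at -0.60 and, named after its value was seen, Rad9a at -0.18. The camera adjusted p was 4.23e-05, with an adjusted p = 0.586 with an estimated correlation. When Whsc1-KO replicates 4 to 6 were left out, 7 were higher and 2 lower, with Brca1 at 0.47, Atr at -0.39 and Rad9a at -0.29. Of 15 tested BCL2 family members 7 were higher and 3 lower (5 lower adjusted over the list alone). The death-promoting Bax had a log2 fold change of 0.56 and the protective Bcl2l1 0.82, and those lower were Bcl2l2, Bcl2a1b and Bcl2, the last named after its value was seen; Bcl2 did not pass without Whsc1-KO replicates 4 to 6 (-0.09). That list did not pass (camera adjusted p = 0.385).

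Most genes of the mature B cell identity list were lower. Of 38 tested members 26 were lower and 2 higher (27 lower adjusted over the list alone), with a median log2 fold change of -0.39. The inhibitory receptor gene Cd72 went from 14766 ± 1849 (SD, n = 7) to 8317 ± 1047 (SD, n = 6; log2 fold change -0.83, limma adjusted p = 2.19e-05). Bcl6 had -1.11, Btla -1.16 and the antigen receptor component Cd79b -0.60. Those higher were Pou2af1 and Fcrla, named after their values were seen. Among 12 follicular B cell genes 9 were lower and 0 higher, also adjusted over the list alone, with the homing receptor gene Ccr7 at -1.20 and the IgE receptor gene Fcer2a at -1.51. The camera adjusted p were 2.46e-06 and 0.00163, and each list had an adjusted p = 0.586 with an estimated correlation. With Whsc1-KO replicates 4 to 6 left out, 18 identity genes and 6 follicular genes were lower, 0 identity genes were higher, and the medians were -0.23 and -0.48. Btla, Cd79b and Fcer2a were then at -0.69, -0.39 and -0.91.

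Of 14 marginal zone genes 3 were higher (4 adjusted over the list alone) and 5 lower: Cd9, Dtx1 and Myof, and Dusp16, Cd1d1, Notch2, Tm6sf1 and Cr2, of which Myof, Notch2, Tm6sf1 and Cr2 were named after their values were seen. The median was 0.01, the mean -0.11 and the direction of the test down, at camera adjusted p = 0.901. The fit without Whsc1-KO replicates 4 to 6 had 4 higher and 1 lower. Myof, Cd1d1, Notch2, Tm6sf1 and Cr2 then did not pass, at 0.26, -0.29, -0.13, -0.10 and -0.07 against 0.28, -0.55, -0.76, -0.45 and -0.89 with all libraries; Dtx1 went from 0.46 to 0.71 and Dusp16 from -0.63 to -0.41. Of 14 B-1 genes 3 were higher and 1 lower, the same adjusted over the list alone: Anxa2 at 2.21, Ahr at 1.18, Itgam at 0.84 and Nid1 at -1.57 (camera adjusted p = 0.445 for the list). Without Whsc1-KO replicates 4 to 6, 6 B-1 genes were higher and 1 lower. Itgam, which is also a myeloid gene, and Nid1 then did not pass, at 0.53 and -0.56 (adjusted p = 0.0621 and 0.0942), while Cd300lf, Plscr1, Ptpn22 and Zbtb32 were higher and Cd5 lower, named after their values were seen.

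Genes of the plasmablast and secretory program rose in part. Of 29 tested members 16 were higher and 1 lower, the same adjusted over the list alone, with a median of 0.52. The endoplasmic reticulum genes Manf, Hyou1 and Fkbp11 rose by 0.83, 0.91 and 1.26, and the gene lower was Zbtb20, at -2.04, named after its value was seen. The camera adjusted p was 0.000719, with an adjusted p = 0.607 with an estimated correlation. Leaving out Whsc1-KO replicates 4 to 6, 8 were higher and 1 lower, with a median of 0.33 and Zbtb20 at -1.04.

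Transcripts of several switched antibody classes were higher. Ighg3 rose from 8345 ± 1708 (SD, n = 7) to 28537 ± 13786 (SD, n = 6; log2 fold change 1.66, SE 0.26, limma adjusted p = 0.00028), Ighg1 by 1.32 and Ighg2c by 2.04. Ighg2c was high in Whsc1-KO replicates 1 to 3, at 4335 to 9188 normalized counts, while replicates 4 to 6, at 256 to 1542, lay within the WT span of 172 to 1587; without the latter its log2 fold change was 3.73. Ighd had a log2 fold change of -1.48 and Ighe -1.36; neither passed when Whsc1-KO replicates 4 to 6 were left out (adjusted p = 0.152 and 0.0751), though Ighe was still at -1.22 and Ighd at -0.55, and Ighg3 was then at 1.06. Ighm, Ighg2b and Igha did not pass, at -0.08, 0.30 and 0.69 (adjusted p = 0.81, 0.305 and 0.276). The list of 8 constant region genes thus had 3 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.521). Counts of a constant region gene include germline transcripts made before recombination, so they do not count switched cells. In the list of class switch recombination and end joining genes 13 of 37 were higher and 5 lower (4 lower adjusted over the list alone). H2afx rose by 0.61, and Parp1, at -0.33, was among those lower, as were Xrcc4 and Prkdc, named after their values were seen; Prkdc did not pass without Whsc1-KO replicates 4 to 6, going from -0.44 to -0.24. Its camera adjusted p was 0.0357, with an adjusted p = 0.586 with an estimated correlation and 0.205 when Whsc1-KO replicates 4 to 6 were left out.

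Lists of metabolic genes were higher or lower as follows; differences between the lists were not tested. Of 28 oxidative phosphorylation genes 24 were higher and 0 lower, also adjusted over the list alone, with Cox5b at 0.54 and Atp5b at 0.56. Among 32 MYC target and ribosome biogenesis genes 28 were higher and 0 lower (29 higher adjusted over the list alone), with the pyrimidine synthesis gene Cad at 0.92 and the polyamine genes Srm and Odc1 at 1.05 and 0.81. Of 21 glycolysis genes 11 were lower and 1, Slc16a1 (named after its value was seen), was higher (12 lower adjusted over the list alone), with Pfkm at -1.17 and the pyruvate dehydrogenase kinase gene Pdk1 at -1.89. Camera adjusted p were 1.51e-08, 6.35e-08 and 0.00275 in that order, with an adjusted p = 0.586 with an estimated correlation for the first and second and 0.625 for glycolysis. Leaving out Whsc1-KO replicates 4 to 6, 18 oxidative phosphorylation and 14 MYC target genes were higher, 1 glycolysis gene was lower and 0 higher with a median of -0.17, and glycolysis and Pdk1 did not pass (adjusted p = 0.13 and 0.103), with Pdk1 at -0.85.

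Lists of LPS responses went both ways. Of 38 TLR4 and NF-kB genes 6 were higher and 15 lower, the same adjusted over the list alone, among them Nfkbie at -0.70, Cd180 at -0.64 and Gadd45b at 0.72. The median was -0.18 and the mean 0.05, and the list did not pass (camera adjusted p = 0.148). When Whsc1-KO replicates 4 to 6 were left out, 4 were higher and 6 lower, with a median of -0.05 and Cd180 at -0.40. Of 34 interferon response genes 4 were higher and 6 lower (5 lower adjusted over the list alone), with Isg15 at 0.80, Bst2 at 0.48 and Ifi44 at -1.67; Cxcl10 and Isg20, named after their values were seen, were the others higher (camera adjusted p = 0.299). The interferon counts moved with the setting: 6 higher and 1 lower without Whsc1-KO replicates 4 to 6, 4 and 18 within the later replicates, and 4 and 21 with a sex score as covariate.

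Of 20 chromatin regulators 4 were higher and 8 lower, the same adjusted over the list alone. Phf19, a Polycomb cofactor, rose by 0.80 and the DNA methyltransferase gene Dnmt1 by 0.52, while Dnmt3a had a log2 fold change of -0.66; Uhrf1 and Ezh2, named after their values were seen, were the others higher. The list did not pass (camera adjusted p = 0.818), and without Whsc1-KO replicates 4 to 6 Dnmt1, Uhrf1 and Ezh2 did not pass (0.27, 0.29 and 0.22; adjusted p = 0.0516, 0.068 and 0.0764), which left 1 higher, Phf19 at 0.48, and 3 lower, Dnmt3a at -0.32 among them. Among 20 genes beside Whsc1 on chromosome 5, 6 were higher and 7 lower, the same adjusted over the list alone, with Letm1 at 0.41 and Fam53a at -0.40. In the fit without Whsc1-KO replicates 4 to 6 Fam53a was at -0.26, and 4 were higher and 3 lower; within replicates 1 to 3 it was 0 and 1. With all libraries their median was 0.12, the mean -0.03 and the camera adjusted p 0.872.

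**Figure D3:**
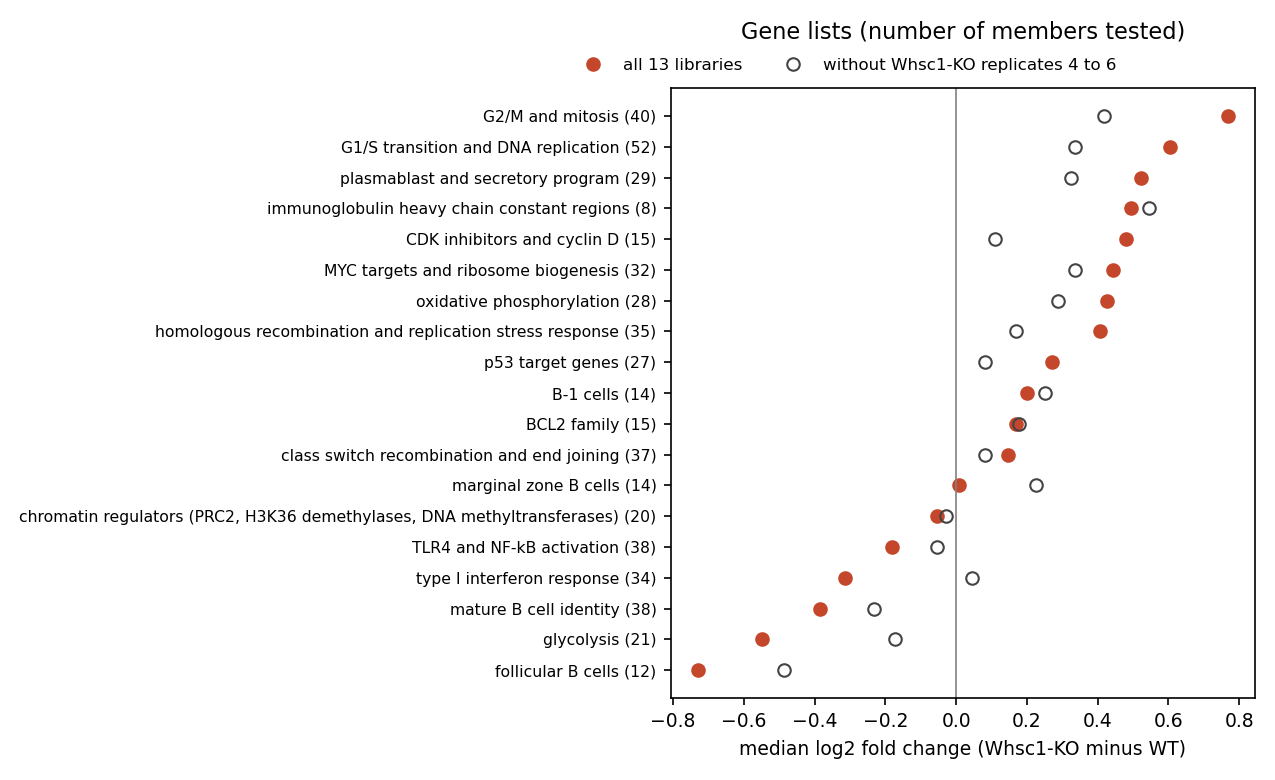
Each line is a list, with the number of its members tested in brackets, and the axis is the median log2 fold change, Whsc1-KO minus WT. Filled points use all 13 libraries and open points leave out Whsc1-KO replicates 4 to 6, which moved the G2/M median from 0.77 to 0.42 and that of glycolysis from -0.55 to -0.17.

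Markers of other blood cells were not even across the Whsc1-KO libraries. Lyz2, an abundant myeloid gene named here after its values were seen, had 7385 to 10272 normalized counts in Whsc1-KO replicates 4 to 6, 193 to 344 in replicates 1 to 3 and 49.2 to 207 in WT. Among 14 monocyte and macrophage markers 11 were higher and 1 lower, also adjusted over the list alone, with Adgre1 at 2.89, Apoe at 1.59 and Ctss, the gene lower, at -0.70. The camera adjusted p was 0.00414, with an adjusted p = 0.586 with an estimated correlation. Of 8 erythroid markers 6 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0268, and adjusted p = 0.586 with an estimated correlation). Hba-a1 had a log2 fold change of 4.23 (SE 1.21, limma adjusted p = 0.00961) and ranged from 17.1 to 529 in WT and from 283 to 41774 in Whsc1-KO, where replicate 6 was the highest. Hba-a1 and Hba-a2 are nearly identical, so how reads were divided between them is uncertain. Leaving out Whsc1-KO replicates 4 to 6, 3 monocyte markers were higher, Adgre1 at 2.11 and Apoe at 1.04 among them, and that list still passed (median 0.65, camera adjusted p = 0.0492), while Hba-a1, Hba-a2, Hbb-bs and the erythroid list did not pass (adjusted p = 0.173, 0.15, 0.18 and 0.066), with log2 fold changes of 2.00, 2.06 and 1.80 for the genes. Alas2 did, at 2.14 (adjusted p = 0.0363), and the median of the erythroid list was then 1.46. Within replicates 1 to 3, 4 of the 8 erythroid markers were higher, with a median of 2.17, and Hba-a1 had 283 to 469 normalized counts in Whsc1-KO against 17.1 to 21.8 in WT.

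Other cell type lists had few tested members. Of 4 neutrophil markers 2, Mmp9 and Csf3r, were higher (3 adjusted over the list alone), and 0 when Whsc1-KO replicates 4 to 6 were left out. Of 7 dendritic cell markers Itgax and Ccr9 were higher and Flt3 and Batf3 lower, the same adjusted over the list alone (camera adjusted p = 0.901). Of 5 T cell markers 1, Cd2, was lower, with a median of 0.14 and a test pointing down (camera adjusted p = 0.872). Of 6 B cell progenitor markers Erg, at -2.60, and Cd93, at -1.35, were lower (camera adjusted p = 0.454, and 0.0187 when Whsc1-KO replicates 4 to 6 were left out). With all libraries this list had an adjusted p = 0.833 with an estimated correlation; the fit with fewer libraries was not run that way. Of 5 endothelial and stromal markers Pecam1 and Cdh5 were lower, with a median of -0.38 and a mean of 0.04 (camera adjusted p = 0.607). The counts of these 3 lists were the same adjusted over the list alone. Without Whsc1-KO replicates 4 to 6 Ccr9, Batf3, Cd2, Cdh5, Pf4 and Ms4a2 did not pass, at 0.73, -0.27, -0.26, -0.55, 0.55 and -0.51. With all libraries they were at 1.68, -1.52, -0.46, -0.70, 1.73 and -1.43, while Cd93 went to -2.14 and Flt3 to -0.64 and still passed. The NK list (0 of 2 called), the megakaryocyte list (Pf4 higher of 3, and 0 adjusted over the list alone) and the basophil and mast cell list (Ms4a2 lower of 2) were too small to test as lists. Itgb3 of the megakaryocyte list was at -0.22 with all libraries (limma adjusted p = 0.664). It was lower without Whsc1-KO replicates 4 to 6, at -1.18 (limma adjusted p = 0.00454). Of 21 handling genes 5 were higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.829). Hspa1b and Hspa1a, near-identical genes, Hsph1, Fosl2 and Hspa8 were higher and Ier5, Ier3, Klf6, Zfp36 and Atf3 lower; Fosl2, Hspa8 and the 5 lower genes were named after their values were seen. Without Whsc1-KO replicates 4 to 6, 4 were higher and 2 lower, with Hsph1 at 0.48 and Ier5 at -0.35.

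**Figure D4:**
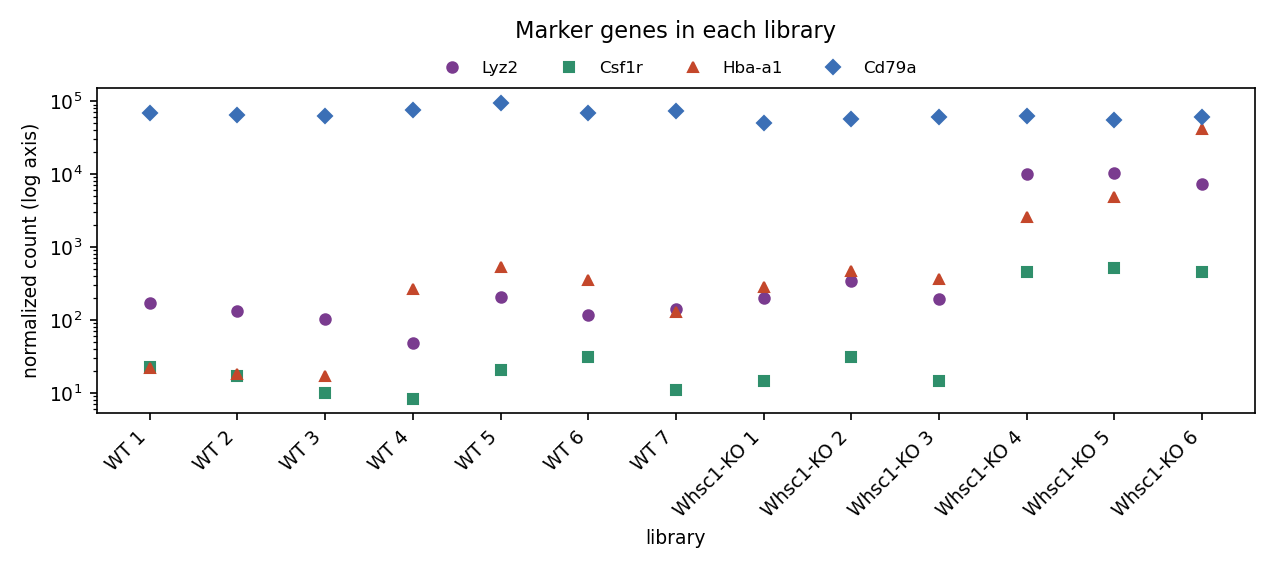
Normalized counts, on a log axis, of the myeloid genes Lyz2 and Csf1r, the erythroid gene Hba-a1 and the B cell gene Cd79a in each library; Lyz2, Csf1r and Cd79a were chosen after their values were seen. Lyz2 lies between 7385 and 10272 in Whsc1-KO replicates 4 to 6 and at 344 or less in the other libraries.

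Xist, named after its values were seen, and Y-linked genes split both groups by sex. WT replicates 1 to 5 and Whsc1-KO replicates 4 and 5 had 93009 to 161721 normalized counts of Xist, and the other libraries 50.6 or less with 5209 or more of the Y-linked Ddx3y. Of 5 sex-linked genes tested by limma 0 passed between the genotypes, also adjusted over the list alone (camera adjusted p = 0.586); it was 0 at an unadjusted p under 0.05 and 0 by edgeR, and 4 Y-linked genes were higher when Whsc1-KO replicates 4 to 6 were left out. The nuclear RNA Malat1, named after its values were seen, had 42340 to 60633 normalized counts in WT replicates 1 to 3 and 15553 to 31217 in later ones, and in Whsc1-KO 53746 to 67515 and 11524 to 17103.

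Across the 29 lists tested, 11 were called higher and 4 lower by camera with the preset correlation, 0 with an estimated correlation and 19 by fry in 1 direction. Of 100 groupings of the 13 libraries, the real one included, 16 gave as many lists with the preset correlation. The number of lists called thus does not separate the genotypes from chance. The 99 other groupings called a median of 10 of the 29 lists, from 1 to 17, though 94 of them called 0 genes. An adjusted p under 0.05 with the preset correlation is therefore weak evidence for a list. A share of groupings was not computed for each single list. The estimated correlation reached 0.887, in the G2/M list.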

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

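The tests without Whsc1-KO replicates 4 to 6 and that of the slope per library were chosen only after the result was seen. Each value in the next paragraph is 1 library that lies far from the others of its group. Of 342 groups of values examined 14 held such a library, and chance gives about 1 in 20.

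In WT replicate 3, Rfx3 had 860 normalized counts against 1177 to 1316 in the other WT libraries, Klf8 1272 against 158 to 275, and Ighg1 420 against 746 to 1095. In WT replicate 4, Hoxa5 had 0 against 1.9 to 5.2, Lcn2 7.2 against 23.8 to 40.1, and Fam53a 2041 against 1754 to 1857, and the neutrophil list scored -2.17 against 0.13 to 0.58, as a mean log2 difference from the WT mean. In WT replicate 5, Itgb3 had 4228 against 1765 to 2527, and the list of CDK inhibitors and cyclin D scored 0.36 against -0.27 to -0.002. In WT replicate 2, Erg had 29.5 against 75.6 to 135 and Rag1 0 against 10.1 to 50.0, and the B cell progenitor list scored -1.99 against -0.04 to 0.97. Hsph1 had 2017 in WT replicate 6 against 2431 to 2741, and Itgax 9.6 in WT replicate 1 against 22.8 to 39.3.

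Genes with a long genomic span were lower in Whsc1-KO, with a Spearman correlation of fold change with span of -0.216 across 11988 protein-coding genes, which are not independent replicates. The slope per library separated the genotypes (two-sided exact permutation p = 0.000583, the smallest the 1716 splits can give). It ran from 0.055 to 0.161 in WT and from -0.176 to -0.058 in Whsc1-KO, so the trend did not rest on a few libraries. A technical length bias that differs between the groups would give the same, so the test cannot exclude it. The correlation of -0.239 without Whsc1-KO replicates 4 to 6 argues against RNA of other cell types there. Given transcript length, GC content and mean level it was -0.11 (95% range over resampled genes -0.128 to -0.094), so a part from those properties cannot be told apart from an effect of span, since the range includes the bound set beforehand. An effect of the genotype on transcription through long genes may remain, as a hypothesis.

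The cell cycle lists were higher in Whsc1-KO. The joint median log2 fold change of their members was 0.352 (95% range 0.318 to 0.385) without Whsc1-KO replicates 4 to 6, which argues against RNA of other cells there as the whole source. It was 0.642 after quantile normalization, which argues against the authors' scaling. It was 0.733 with the sex score, but sex partly followed the replicate sets in Whsc1-KO, so this fit cannot exclude sex. The G2/M list scored -0.044 and -0.067 in male WT replicates 6 and 7, within -0.291 to 0.26 in female WT. It scored 1.045 in male Whsc1-KO replicate 6, against 1.062 and 1.099 in female replicates 4 and 5. For that list these scores argue against the sex of the donors as the whole source. The part lost with replicates 4 to 6 stays open, as Whsc1-KO replicates 1 to 3 are all male and WT holds both sexes, and it stays open whether more cells in cycle or a change within cycling cells underlies the rest, since no cell counts are held here.

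The tested Hoxa genes were higher in Whsc1-KO. The filter fixed the direction, though not the size, since each of these genes lay below the filter's minimum in every WT library. Their median log2 fold change was 5.661 without Whsc1-KO replicates 4 to 6 and 6.103 with the sex score, which argues against RNA of other cell types in those libraries and against the sex of the donors. The median of the 7 other genes tested within 1 Mb was -0.149 (-0.71 to 0.18), which argues against a change of the whole region. A candidate explanation, as a hypothesis only, is that silencing of the cluster in B cells depends on Whsc1. Progenitor cells in every Whsc1-KO library stay open. CD43 depletion is meant to remove those that carry CD43. Myeloid RNA remained in Whsc1-KO replicates 4 to 6, with Lyz2 at 7385 to 10272 normalized counts. The depletion therefore need not have been complete. Of genes active in progenitors Erg, Cd93 and Flt3 were lower, at -2.60, -1.35 and -1.17. Kit and Il7r did not pass, at 0.77 and 0.74 (limma adjusted p = 0.305 and 0.127). These values do not decide the question. Cd93 and Flt3 had WT means of 7094 and 8923 normalized counts, too high to report a few progenitor cells.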

How the results depend on the processing

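The settings on sets of replicates, and those with an early or later term, were chosen after seeing the data. The counts of genes and lists stayed within 1.5 times, and Whsc1 kept its direction and call, under the alternatives run, with these exceptions. At a log2 fold change of 1 or more in size 679 genes were higher and 717 lower, and Whsc1, at -0.54, falls short of that size by construction. Without Whsc1-KO replicates 4 to 6 the counts were 1947 and 2177, and with replicates 1 to 3 only 947 and 1222; fewer libraries enter these fits. The number of lists was 0 with camera's estimated correlation and 27 by fry in either direction, the cause was not tested. Leaving out 1 library gave 3135 to 3776 genes higher, 3148 to 3723 lower, 13 to 15 lists, and -0.58 to -0.48 for Whsc1. The replicate numbers do not pair the libraries (correlations of same-numbered deviations -0.108 to 0.206; 2 Whsc1-KO libraries correlated best with the WT library of their number), and the replicate block gave 3023 genes higher, 3085 lower and 12 lists. Of the named genes' values under alternatives 4787 were on the same side, 166 weaker, 58 stronger and 39 of opposite sign, and of the lists' 831, 30, 9 and 25.

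Values whose direction turned follow, as log2 fold changes of genes and medians of lists (a list turns with its test, so its median may not). Apart from Pf4 none had passed, and the cause was not tested unless stated. With replicates 1 to 3 only, Pf4 was -0.344, Ccl5 -0.432, Cd247 -0.464, Ighg2b -0.052, Ighm 0.25, Il7r -0.151, Itga2b 0.051, Lcn2 -1.013, Mmp8 -0.848, Prf1 0.232, the marginal zone list 0.204 and the interferon list 0.251. Without Whsc1-KO replicates 4 to 6, Cd247 was -0.166, Ighg2b -0.037, Ighm 0.044, Il7r -0.058, Lcn2 -0.749, the marginal zone list 0.225 and the interferon list 0.044. The signal of Lcn2 lay in the libraries left out, at a mean of 891 normalized counts against 16.0 in Whsc1-KO replicates 1 to 3. With replicates 4 and later only, Ddx3y was -2.08, Eif2s3y -2.184, Uty -1.907, Itgb3 0.652, Rag1 0.507, the B cell progenitor list 0.575, chromatin regulators -0.1, the dendritic list -0.096 and the sex-linked list -2.08. Of these libraries WT replicates 6 and 7 and Whsc1-KO replicate 6 were male by Ddx3y, so the Y-linked genes followed the sex of the libraries kept. With library weights, Ddx3y was -0.1, Eif2s3y -0.223, Uty -0.158, Itgb3 0.479, Rag1 1.002, the B cell progenitor list 0.846, the T cell list 0.409, the dendritic list 0.002 and the handling list -0.138. Ccl5 was -0.014 by edgeR, -0.012 by DESeq2 and -0.012 in the authors' deposited table, and Itgb3 0.033, 0.04 and 0.031. With the sex score Itgb3 was 0.05 and the dendritic list 0.034, and with the early or later term as well Itgb3 was 0.121, Rag1 0.027 and the dendritic list 0.01. The dendritic list was -0.094 with the replicate block and the marginal zone list 0.009 by the Wilcoxon test. With no filter the T cell list was 0.456 and the endothelial list 0.443, and with a minimum of 100 the handling list was -0.107. Leaving out 1 library gave ranges of -0.089 to 0.273 for Ccl5, -0.201 to 0.013 for Ighm, -0.451 to 0.061 for Itgb3, -1.105 to 0.019 for Rag1, -0.071 to 0.183 for the handling list, 0.074 to 0.133 for the genes beside Whsc1, -0.155 to 0.163 for the dendritic list and -0.04 to 0.037 for the marginal zone list.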

Other observations

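The values without Whsc1-KO replicates 4 to 6 and with an early or later term were chosen only after the result was seen. Thresholds of the other tests in this part were set before those tests were run. Some of these tests took up patterns already seen in these data, such as that of the kappa segments. Outside the Hoxa cluster 5 homeobox genes of the Hox family were tested, and Hoxb3, Hoxb4, Hoxb6, Hoxb7 and Hoxc4 were all higher. The others had too few reads to test. In WT the highest libraries of Hoxb6, Hoxb7 and Hoxc4 had 4.57, 3.65 and 4.36 normalized counts, below the filter's minimum. These genes were tested only because all Whsc1-KO libraries reached that minimum, so the filter fixed their direction. Hoxb6, Hoxb7 and Hoxc4 had WT means of 2.4, 2.18 and 1.34 normalized counts and Whsc1-KO means of 32.1, 23.9 and 27.2, with log2 fold changes of 3.38, 2.96 and 3.90 (limma adjusted p = 3.66e-05, 4.21e-05 and 4.95e-05). Hoxb4 rose from 82.5 to 184, a log2 fold change of 1.22. These genes were chosen after their values were seen. Of the pathways in the authors' deposited enrichment tables, the spliceosome had 77 listed genes higher and 5 lower, the proteasome 29 higher and 1 lower, and the ribosome 25 higher and 67 lower, against 4337 higher and 3779 lower over the authors' whole list. These pathways were chosen after their counts were seen.

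The imprinted genes named here were chosen after their values were seen. Dlk1, Meg3 and Rian, which share a locus, rose by 3.06, 3.28 and 2.96 on the log2 scale (limma adjusted p = 3.76e-05, 0.000113 and 0.000412). Among 25 other imprinted genes tested 6 were higher (24%), against 26.1% of the remaining genes (1-sided Fisher's exact p = 0.667), which argues against a rise of imprinted genes as a class. Peg3 rose by 4.16, and Sgce had a log2 fold change of -3.11. The WT mean of Peg3 was 1.1 normalized counts and the Whsc1-KO mean of Sgce 1.4. At these means no library of that group could reach the filter's minimum, so the filter fixed the direction of both genes.

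Variable segments of the immunoglobulin loci shifted with position. Across 106 kappa segments the Spearman correlation of fold change with distance from the joining segments was -0.403 (permutation p = 1e-04, the smallest the permutations can give), with 21 segments higher and 10 lower. Across 109 heavy chain segments it was -0.381 (permutation p = 2e-04), with 4 higher and 13 lower. These were -0.437 and -0.397 without Whsc1-KO replicates 4 to 6. Use of segments nearer the joining segments may have shifted in Whsc1-KO cells, but segments are not independent replicates, near-identical segments share reads, and a few expanded clones could give the same trend.

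Replicates 1 to 3 and the later replicates differed in both genotypes. Across genes, the later minus earlier difference in WT had a Spearman correlation of -0.01 with that in Whsc1-KO. Malat1 was nonetheless lower in the later replicates of both genotypes (15553 to 31217 against 42340 to 60633 in WT, 11524 to 17103 against 53746 to 67515 in Whsc1-KO) and Hba-a1 higher (130 to 529 against 17.1 to 21.8, and 2580 to 41774 against 283 to 469). The myeloid RNA of Whsc1-KO replicates 4 to 6 and a mix of sexes that shifts in opposite ways in the genotypes could lower the correlation as well (sex-linked genes were left out of it), so a batch shared by both genotypes stays open. With an early or later term 3927 genes were higher and 3951 lower in Whsc1-KO.

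Other groupings of the 13 libraries, 100 drawn with the real one included, were fitted with limma to see what chance gives. For the genes higher, 1 of 100 groupings, the real one, gave as many as 3636, and the highest of the others gave 2396. For the genes lower it was 1 of 100 with 3588, and the highest of the others gave 2477. That grouping set WT replicates 2 to 7 against all Whsc1-KO libraries and WT replicate 1, so it nearly kept the genotypes. Of the 99 other groupings 94 called 0 genes. Where neither group came within 1 library of a genotype, a grouping called 2 genes at most. No other grouping drawn gave as many for either count, and 1 of 100 is the smallest share these draws can give. The draws cannot tell genotype apart from sex or RNA of other cells, which also differed between the groups. For the number of gene lists, other groupings did give as many: the real grouping gave 15, 16 of 100 gave as many, and the highest of the others gave 17. Of the other groupings 13 called 15 or more lists while calling 0 genes.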
